A study of Mus musculus with 2 samples.

How the data were processed

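DNase-seq libraries were made from the urinary bladder of 4-day-old female mice of strain B6CASTF1/J, with 1 library for each of 2 biological replicates. Per the labels, the tissue came from separately numbered females under a shared donor identifier, and the replicates form a single group. Each sample had 5 deposited files: a list of false discovery rates per stretch of bases, a looser and a stricter peak list, a list of footprints and a description of the files. Positions refer to assembly mm10. According to the descriptions, the peaks, rates and footprints of a sample were derived from that sample's own filtered alignments, with further input files that the descriptions list. The aligner, the peak caller, the footprint caller, their versions, the read filters and the thresholds are not given in the sources used here.

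The height of a peak was the only column of the peak lists that varied beside the position, and it is the signal that the authors deposited. Its scale is not given for the peak lists, and the descriptions name a signal normalized to read depth only for another output. Each height was checked to be a whole multiple of 1 step per sample within 0.02 steps, so it counts events in units of that step, and the ratio of the steps gives the relative depth if both libraries were scaled to the same total. The deposited p-value of the rate lists is a false discovery rate (q-value) per stretch of bases, listed from 0 to 0.05. In the deposited footprint lists the p-value column holds 0.01 throughout, so footprints could not be ranked. The looser and stricter lists were told apart by length and by the lowest listed rate inside each peak, which reached 0.0499 in the looser and 0.000997 in the stricter lists. The looser list was used except where stated. Total read depth is not given in the sources used here, and the precision of a height was taken from its number of steps by an exact Poisson interval.

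The tests, gene lists, motifs and thresholds were chosen before the data were examined, apart from those named below. All analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9. Overlap counts were checked with bedtools 2.31.1, which gave the same numbers of overlapping peaks. Peaks of the replicates were called shared where they overlapped by at least 1 bp. Overlapping peaks of both replicates were merged into regions. A region was shared if it held a peak of each. Its height in a replicate was that of its tallest peak there, and its centre was the mean of the centres of these tallest peaks. Chance levels came from 20 shuffles within each chromosome, outside assembly gaps. Heights were compared on the log2 scale without a pseudocount, because no height was 0.

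Genes were the 21938 protein-coding genes of GENCODE M21. A region was proximal if its centre lay within 1000 bp of a TSS. A gene had a promoter peak if a peak overlapped the 500 bp on either side of any of its TSSs, and the tallest such peak gave its height. Windows of this kind can be shared by neighbouring genes, which held for Egfl7 and Gm20532, Neurod1 and Cerkl, Hoxa3 and Gm28308, Hoxd3 and Hoxd4, and Itgam and Gm49368. A set of 18 lists with 260 genes covered housekeeping, urothelium, smooth muscle, fibroblast and mesenchyme, mesothelium, endothelium, immune, peripheral glia and neurons, erythroid, adipocyte, striated muscle, hepatocyte, central nervous system, kidney, other endoderm epithelia, germ cell, immediate early and stress, and proliferation genes. All of these genes were matched to the annotation by symbol.

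The share of each list with a promoter peak in both replicates was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18 lists. It was also compared with 10000 random lists matched on 10 strata of promoter GC content. Distal regions, over 1000 bp from any TSS, were assigned to the nearest protein-coding TSS within 100 kb. The median number per gene was compared with 10000 random lists matched on 5 strata of the distance between the neighbouring TSSs. Differences between replicates were log2 ratios of heights (replicate 2 over replicate 1), centred on the median of all shared regions. Lists with at least 3 measured genes were compared with 10000 random lists of the same size, with adjustment over 30 tests. An adjusted p under 0.05 was called past the threshold. Genes are not replicates, so these tests describe the libraries and not a population of animals. The 39 Hox genes were counted by cluster and by paralogue group, and densities on X and Y used the sequence outside assembly gaps.

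For 30 motifs, written as consensus strings, matches on either strand were counted in the central 150 bp of shared distal regions. The background was 1 shuffle of each window that keeps its dinucleotides. For footprints, matches anywhere in shared regions were used, promoters included. A match counted as footprinted if at least 50% of its bases lay in a footprint. It was set against the position mirrored about the midpoint between the ends of its region, for motifs with at least 30 matches. Ratios carry 95% intervals for counting error only.

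Genes were named by a rule that was also set in advance. It takes the 3 members of each list with the highest mean rank of promoter height and 4 members without a promoter peak in either replicate, first in list order, with every Hox gene. It adds the 10 shared distal regions with the highest mean rank and the 10 genes with most shared distal regions, and in each replicate the 5 tallest peaks that overlap none of the other. Some genes that the rule picks are not reported here. Genes named beyond this rule were chosen after their values were seen. They include Acta2, Des, Actg2, P2rx1, Foxf1, Tbx18, the uroplakins, Fos, Fosb, Ier2, Klf4, Col1a1, Shh and Grhl2 for their distal regions, and all genes of the signalling lists.

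The alternatives were a reciprocal overlap of 50%, the stricter peak lists, equal numbers of the tallest peaks, a promoter window of 1000 bp, a proximal distance of 2500 bp, assignment within 50 kb, quantile normalization, motif windows of 300 bp, GC-matched windows outside peaks, any overlap of a motif with a footprint, and each replicate alone. GC-matched windows were the closest in GC of 20 random windows on the same chromosome. Alternatives chosen after seeing the data were peaks at or above the low point between the modes of height (0.386 and 0.459, found on bins of 0.25 log2 units of the stricter lists), calls by GC-matched random lists, the mean in place of the median for distal regions, and the stricter peak lists for footprints. Patches were also defined then, as runs of at least 5 low peaks of the stricter list with gaps of at most 3 kb. Further lists, drawn up once the data had been seen, held Hedgehog, retinoic acid, BMP and TGF-beta, Wnt and Notch genes, and taste and olfactory receptors, of which 1 gene was not matched to the annotation.

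The steps were tested on simulated data. For promoters, 9 lists of 20 random genes were simulated at a true share of 95% and 9 at 62%, in the same 21938 genes. Fisher's exact test with adjustment called 9 of the 9 raised lists and, falsely, 1 of the 9 others. The lists tested held 7 to 25 genes, and neither shorter lists nor a bias in promoter GC was simulated. For differences between replicates, lists of 20 genes shifted by 0.5 on the log2 scale (SD 0.35 per gene, 9000 genes) were called in 10 of 10 cases and unshifted lists in 0 of 10, by the unadjusted permutation p. The lists tested had 3 to 19 measured genes and an adjusted p, so these simulations do not give the power of the reported tests. Bases with a listed false discovery rate outside peaks were counted but not otherwise used here.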

Results

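DNase-seq maps open chromatin by sequencing the ends of DNA fragments that DNase I releases from nuclei. It was measured in the urinary bladder of 4-day-old female mice of strain B6CASTF1/J, an F1 hybrid between a C57BL/6J and a CAST/EiJ parent. The labels give 1 group of 2 biological replicates from separately numbered females, listed under a shared donor identifier, so no contrast between groups existed and the spread between the samples may be partly technical. Peaks were called by the authors in each sample alone. At the looser of the 2 deposited thresholds, replicate 1 had 96518 peaks covering 20.3 Mb and replicate 2 had 122870 peaks covering 23.1 Mb, with median widths of 200 and 180 bp. The stricter lists held 61623 and 77545 peaks.

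The height of a peak, as the authors deposited it, had a median of 0.512 in replicate 1 and 0.321 in replicate 2. In each sample every height was a whole multiple of a fixed step (100% of peaks, tolerance 0.02 steps), which was 0.00466 in replicate 1 and 0.00417 in replicate 2. If both libraries were scaled to the same total, replicate 2 was 1.12 times as deep; the total depth of either library is unknown here. The median peak was 110 steps high in replicate 1 (95% exact Poisson interval 90.4 to 133) and 77 steps high in replicate 2 (60.8 to 96.2), intervals that cover counting error only. Heights in the stricter lists had a low and a tall mode, parted at 0.386 in replicate 1 and 0.459 in replicate 2.

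**Figure D1:**
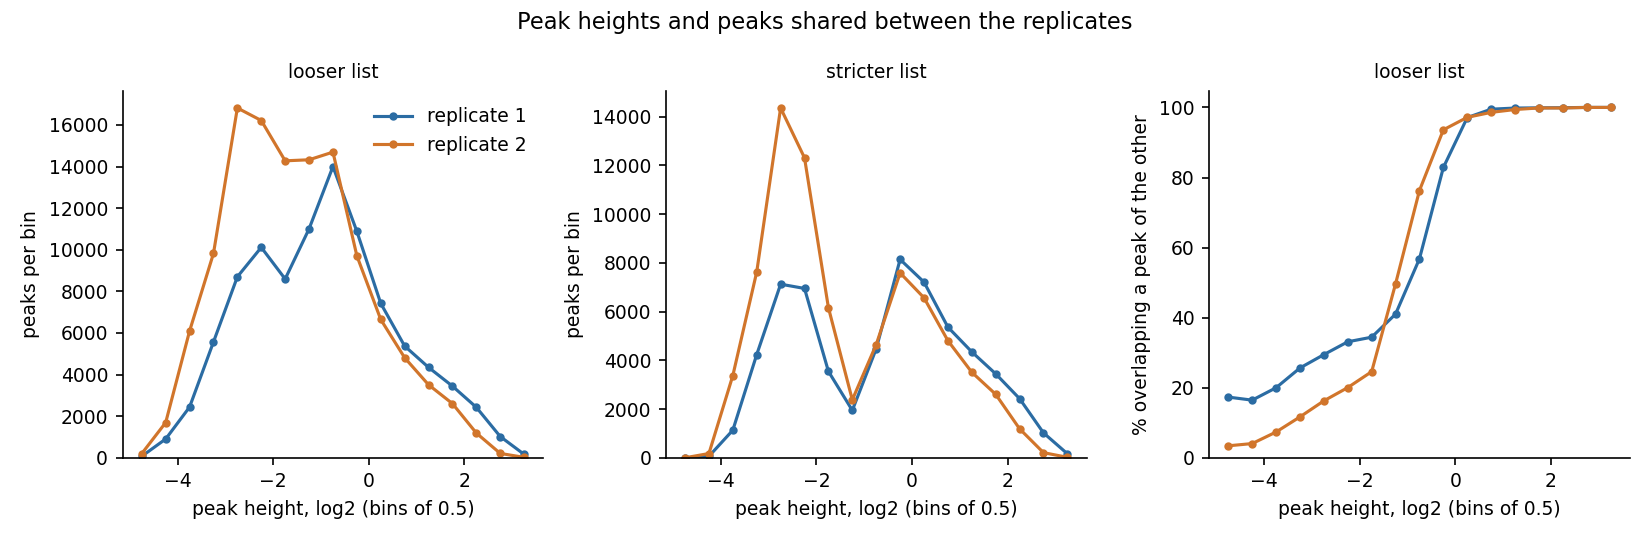
Number of peaks per bin of log2 peak height in the looser and the stricter list, and the percent of peaks of the looser list that overlap a peak of the other replicate, for replicate 1 (blue) and replicate 2 (orange). The stricter lists have a low and a tall mode, and almost all of the tallest decile of peaks were shared (99.9% and 99.2%).

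Tall peaks were called in both replicates far more often than low ones. Whether a site called in only 1 replicate differed in openness between the animals was not tested. Of the peaks in replicate 1, 58.4% overlapped a peak of replicate 2 by at least 1 bp, and 46.6% of the peaks in replicate 2 overlapped a peak of replicate 1, against 2.03% and 1.59% for shuffled peaks (SD 0.0574 and 0.0377 over 20 shuffles). Sharing ran from 99.9% and 99.2% in the tallest decile of peaks to 23.6% and 8.07% in the lowest decile. Above the low point between the modes of height, 70.5% and 86.6% of peaks were shared. Log2 heights over the 53490 shared regions correlated with Pearson's r = 0.966 and Spearman's rho = 0.961, a relation across regions, which are not independent replicates. The median log2 ratio of heights, replicate 2 over replicate 1, was -0.28 (SD 0.40 over regions), from 0.06 in the lowest quartile of shared regions to -0.44 in the tallest.

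Shared regions clustered at gene starts. Of the 53490, 42.6% had their centre within 1000 bp of a transcription start site (TSS), 4.72% lay in other exons, 24.4% in introns and 28.3% between genes, where shuffled regions gave 6.38%, 3.43%, 40.1% and 50.1%. Taken alone, 33.0% of the regions in replicate 1 and 27.2% of those in replicate 2 were near a TSS. Peaks found in only 1 replicate were near a TSS in 19.6% (replicate 1) and 13.2% (replicate 2) of cases. A promoter peak, within 500 bp of an annotated TSS, was present in both replicates at 13670 of 21938 protein-coding genes (62.3%). The median tallest promoter peak was 2.44 in replicate 1 and 1.80 in replicate 2.

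Genes of the muscle coat of the bladder had open promoters almost throughout. In the smooth muscle list, 19 of 21 genes (90.5%) had a promoter peak in both replicates, against 62.3% of the other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg-adjusted p = 0.0137 over 18 lists). The tallest promoters were those of Srf, a transcription factor that drives contractile genes (chromosome 17, 46548329 to 46556175), at 3.56 ± 0.80 (SD, n = 2), Tpm2, a tropomyosin (chromosome 4, 43514711 to 43523765), at 2.57 ± 0.630, and Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), at 2.42 ± 0.257. Acta2 and Des, the smooth muscle actin and the muscle intermediate filament, had promoter peaks of 0.995 ± 0.187 and 1.48 ± 0.308. Actg2, the enteric smooth muscle actin, and P2rx1, the ATP receptor of the bladder muscle, had a peak in replicate 1 alone, at 0.657 and 0.591. Against random lists matched on promoter GC content, which had a peak at 72.6% of genes on average, the list was not past the threshold (adjusted p = 0.107), nor was it in the stricter peak lists (61.9% of genes, Fisher's exact test, adjusted p = 0.662). In replicate 1 alone all 21 genes had a peak and the list passed against the random lists (permutation test, adjusted p = 0.0108). It did not pass against them in replicate 2 alone (90.5%, adjusted permutation p = 0.197).

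Connective tissue genes had open promoters in most cases. Of the fibroblast and mesenchyme list, 17 of 20 genes (85.0%) had a promoter peak in both replicates, which did not pass Fisher's exact test after adjustment (p = 0.0529). It did pass against random lists matched on promoter GC, which had 64.1% on average (adjusted p = 0.0144), and by Fisher's exact test in replicate 1 alone (95%, adjusted p = 0.00952) but not in replicate 2 alone (85.0%, adjusted p = 0.103). In the stricter lists (75.0%) neither test passed (adjusted p = 0.0917 by Fisher's exact test and 0.0846 against random lists). The tallest promoters belonged to Col1a1, a fibrillar collagen (chromosome 11, 94936224 to 94953042), at 2.78 ± 0.133 (SD, n = 2), Gli1, a transcription factor activated by Hedgehog signals (chromosome 10, 127329882 to 127341974), at 2.49 ± 0.337, and the mesenchymal filament gene Vim (chromosome 2, 13573927 to 13582826), at 2.07 ± 0.115. Foxf1 and Tbx18, transcription factors of visceral and urinary tract mesenchyme, reached 1.54 ± 0.325 and 1.51 ± 0.0717, and Bmp5 had no promoter peak in either replicate. Of the mesothelium list, which marks the lining of the body cavity, 5 of 8 genes (62.5%) had a peak in both replicates (Fisher's exact test, adjusted p = 1). These included Msln at 1.54 ± 0.0138, Aldh1a2, a retinoic acid synthase, at 1.35 ± 0.257 and Wt1 at 1.06 ± 0.0731.

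Urothelial genes, those of the bladder's lining epithelium, did not have a promoter peak more often than other genes. A peak in both replicates was present at 14 of 25 genes (56.0%, Fisher's exact test, adjusted p = 0.607), and the median height where a peak was called was 0.878 in replicate 1 and 0.615 in replicate 2, against 1.20 and 0.863 for the smooth muscle list. Differences between these lists in share or height were not tested. Klf5, a transcription factor of epithelial progenitors (chromosome 14, 99298691 to 99315036), was the tallest at 2.68 ± 0.975 (SD, n = 2), before the adhesion gene Cdh1 (chromosome 8, 106603351 to 106670246) at 1.30 ± 0.157 and the epithelial ETS factor Elf3 (chromosome 1, 135253575 to 135258568) at 0.974 ± 0.169. Among the uroplakins, the membrane proteins that make the urothelial surface plaques, Upk1b and Upk3a had peaks of 0.744 ± 0.298 and 0.724 ± 0.280. Upk2 had a peak in replicate 1 alone (0.806), and Upk1a and Upk3b had none. Krt14 and Krt20, keratins of basal and of superficial cells, had none either. In the stricter peak lists the share was 32%, below that of the other genes (Fisher's exact test, adjusted p = 0.0389).

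Among the lists of vessels, blood, nerves and fat, the immune and erythroid lists had fewer open promoters than the other genes. The endothelium list had 9 of 19 genes with a peak in both replicates (47.4%, Fisher's exact test, adjusted p = 0.283), led by Egfl7 at 1.27 ± 0.198 (SD, n = 2), Esam at 0.936 ± 0.145 and Sox17 at 0.841 ± 0.326, while Pecam1, Erg, Sox18 and Emcn had none. Of the immune list, 3 of 17 genes had one (17.6%, Fisher's exact test, adjusted p = 0.00129): Coro1a, an actin regulator of leukocytes, at 2.60 ± 0.648, and Cd68 and Cd14, both of macrophages, at 0.595 ± 0.0251 and 0.532 ± 0.163. Ptprc, Adgre1, Csf1r and Spi1, genes of all leukocytes or of macrophages, had no promoter peak. In the list of peripheral glia and neurons, 6 of 15 genes had one (40%, Fisher's exact test, adjusted p = 0.137), a share below that of random lists matched on promoter GC (69.2% on average, adjusted p = 0.0212) that did not pass in replicate 1 alone (60%, adjusted p = 0.392) or replicate 2 alone (46.7%, adjusted p = 0.0604). Hand2, a factor of autonomic neurons and of mesenchyme, had 1.12 ± 0.464 and the neuronal RNA-binding protein gene Elavl4 had 1.02 ± 0.117, while Sox10, Chat and Th had none. Of the erythroid list, 2 of 11 genes had a peak in both replicates (18.2%, Fisher's exact test, adjusted p = 0.0111), Epor at 0.869 ± 0.00375 and Tal1 at 0.656 ± 0.120, and the globin genes Hbb-bs and Hbb-bt had none, as had Gata1 and Klf1. Of the adipocyte list, 4 of 7 genes had one (57.1%, Fisher's exact test, adjusted p = 1), with Cebpa at 4.38 ± 0.808, Plin1 at 1.36 ± 0.290 and Cidea at 0.674 ± 0.0314, and none at Adipoq or Fabp4.

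Genes of tissues other than the bladder mostly lacked a promoter peak. No promoter of the hepatocyte list was open in either replicate, among them Alb, Apoa1, Apoa2 and Ttr (0 of 15, Fisher's exact test, adjusted p = 7.85e-06). The other lists below the rest of the genes were striated muscle (3 of 13, 23.1%, adjusted p = 0.0137), other endoderm epithelia (2 of 12, 16.7%, adjusted p = 0.00742), germ cell (2 of 11, 18.2%, adjusted p = 0.0111), central nervous system (5 of 15, 33.3%, adjusted p = 0.0475) and kidney (2 of 9, 22.2%, adjusted p = 0.0475), all by Fisher's exact test. Open members were Pygm, the muscle glycogen phosphorylase, at 1.62 ± 0.690 (SD, n = 2), Ckm, the muscle creatine kinase, at 0.834 ± 0.224, and Nkx2-5 at 0.399 ± 0.140. Cela1, Ins1 and Lhx1 had 1.37 ± 0.293, 0.372 ± 0.0539 and 0.886 ± 0.0380. Gfap, the astrocyte filament gene that glia of peripheral nerves also express, had 2.00 ± 0.492 and Syn1 had 1.12 ± 0.0625. Dazl, a germ cell RNA-binding protein gene, stood at 2.49 ± 0.359 and Sycp1 at 0.383 ± 0.0541. Neither replicate had a promoter peak at Myh6, Myl7, Tnnt2 or Tnni3 of the heart, Neurod1, Neurod6, Neurog2 or Rbfox3 of neurons, Umod, Slc12a1 or Slc34a1 of the kidney, Pdx1, Cdx1, Cdx2 or Vil1 of the pancreas and gut, or Prm1, Prm2, Tnp1 or Zp3 of germ cells. The calls for the central nervous system and kidney lists ended when either replicate was used alone (central nervous system 53.3% and 40%, Fisher's exact test, adjusted p = 0.534 and 0.103; kidney 44.4% in each, adjusted p = 0.403 and 0.353). The central nervous system call also ended with a promoter window of 1000 bp (53.3%, Fisher's exact test, adjusted p = 0.513) and above the low point of heights (33.3%, adjusted p = 0.0845). The germ cell call ended in replicate 2 alone, where 7 of 11 promoters had a peak (63.6%, Fisher's exact test, adjusted p = 1).

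Promoters of the housekeeping, immediate early and stress, and proliferation lists were open without exception. All 20 housekeeping genes had a peak in both replicates (Fisher's exact test, adjusted p = 0.000868), as had all 12 immediate early and stress genes (adjusted p = 0.0130) and all 10 proliferation genes (adjusted p = 0.0305). Among housekeeping genes the tallest were the translation factor gene Eef2 (chromosome 10, 81176631 to 81182498) at 7.32 ± 1.22 (SD, n = 2), Vcp at 6.58 ± 1.35 and Ppia at 6.46 ± 1.90. Jund and Jun, subunits of the AP-1 transcription factor, had 6.15 ± 0.968 and 5.11 ± 1.02, and Egr1, a factor induced by growth signals, had 4.54 ± 0.740. The DNA replication genes Mcm5 and Pcna had 5.71 ± 1.24 and 4.24 ± 0.543, and the cyclin gene Ccna2 had 4.73 ± 0.767. Matched on promoter GC, random lists had a peak at 88.3% (immediate early) and 71.1% (proliferation) of genes. Against them, the immediate early and proliferation lists were not past the threshold (permutation test, adjusted p = 0.496 and 0.0531). The proliferation list did pass in the stricter lists (adjusted permutation p = 0.0135) and above the low point of heights (0.0347). The housekeeping list passed against its random lists (adjusted permutation p = 0.0357), though in neither replicate alone (0.0878 and 0.0727) nor with a promoter window of 1000 bp (0.0572). Genes are not replicates, so these tests describe the libraries at hand.

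**Figure D2:**
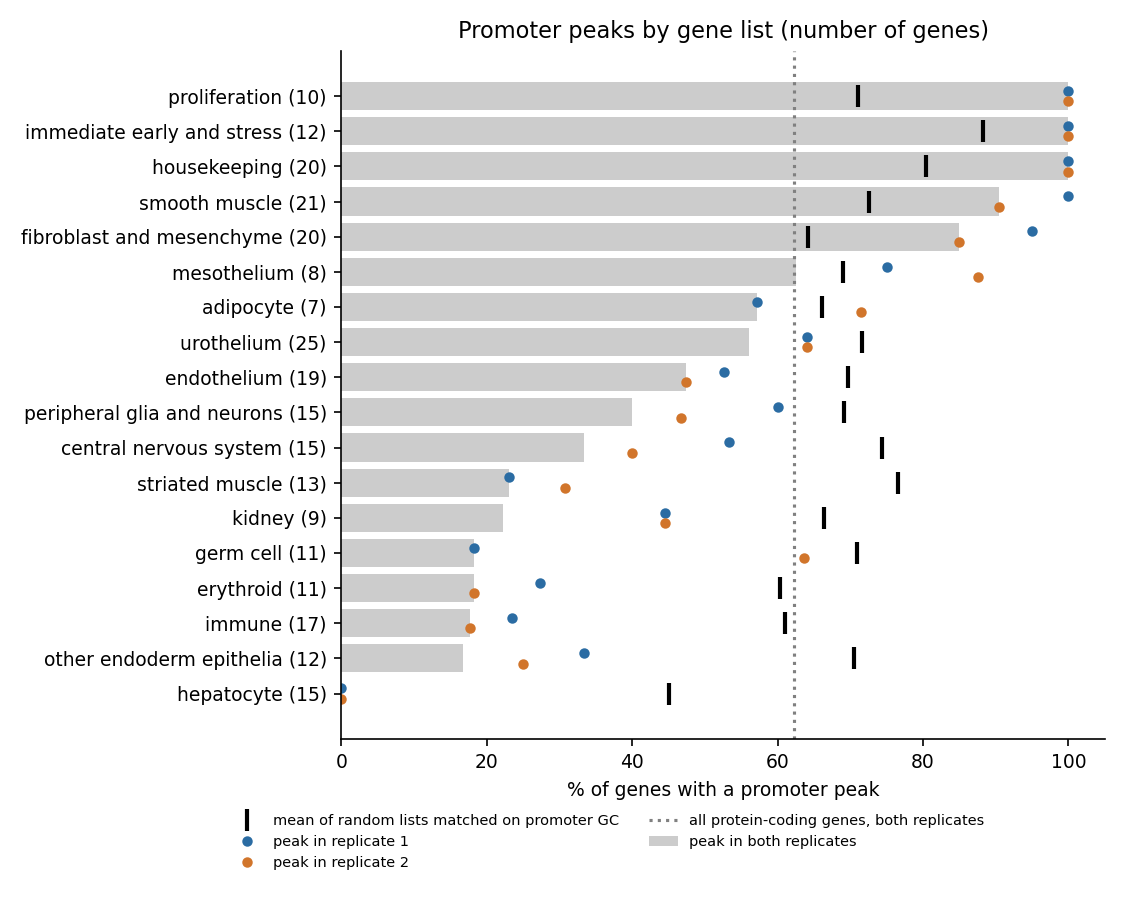
Percent of each list's genes with a promoter peak in both replicates (grey bars), in replicate 1 alone or replicate 2 alone taken by itself (blue and orange points), with the mean of random lists matched on promoter GC (black ticks) and the share of all protein-coding genes (dotted line, 62.3%). Smooth muscle genes reach 90.5% and hepatocyte genes 0%.

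Among the Hox genes, which set position along the body axis, the Hoxa cluster had the most shared regions. Hoxa (chromosome 6, 52155590 to 52260880) held 52 shared regions, 4.94 per 10 kb, where the genome had 0.202, and 9 of its 11 genes had a promoter peak in both replicates. Hoxd (chromosome 2, 74668310 to 74765142) had 1.86 per 10 kb with 4 of 9 promoters, Hoxb (chromosome 11, 96194316 to 96368256) 0.460 with 2 of 10, and Hoxc (chromosome 15, 102921103 to 103036852) 0.346 with 2 of 9. The tallest promoters were Hoxa10 at 3.41 ± 0.872 (SD, n = 2), Hoxa7 at 3.19 ± 1.45, Hoxc10 at 3.03 ± 0.00603, Hoxa4 at 2.5 ± 0.475 and Hoxd8 at 2.01 ± 0.586. By position in the clusters, promoters were open at 3 of 12 genes of paralogue groups 1 to 4, 6 of 15 of groups 5 to 9 and 8 of 12 of groups 10 to 13. In the stricter lists these counts were 3, 5 and 4, and in replicate 1 alone 8, 9 and 11. The 8 open genes of groups 10 to 13 were Hoxa10, Hoxa11, Hoxa13, Hoxc10, Hoxc13, Hoxd10, Hoxd11 and Hoxd12. Hoxa3, Hoxa5 and Hoxa9 were also open, and Hoxb5 (1.48 ± 0.402) and Hoxb6 (0.945 ± 0.0987) were the open Hoxb genes. Hoxa2, Hoxa6, Hoxb7, Hoxb13, Hoxc4, Hoxc12, Hoxd1, Hoxd3, Hoxd4, Hoxd9 and Hoxd13 had a promoter peak in replicate 1 alone. Hoxb1, Hoxb2, Hoxb3, Hoxb4, Hoxb8, Hoxb9, Hoxc5, Hoxc6, Hoxc8, Hoxc9 and Hoxc11 had none in either. In replicate 1 alone, promoters were open at 11 Hoxa, 4 Hoxb, 4 Hoxc and 9 Hoxd genes, against 9, 2, 2 and 4 in replicate 2 alone, and the density of Hoxc regions was 2.25 against 0.346. Above the low point of heights the density was 2.18 for Hoxa and 1.03 for Hoxd, and in the stricter lists 1.14 for Hoxd and 0.115 for Hoxb.

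**Figure D3:**
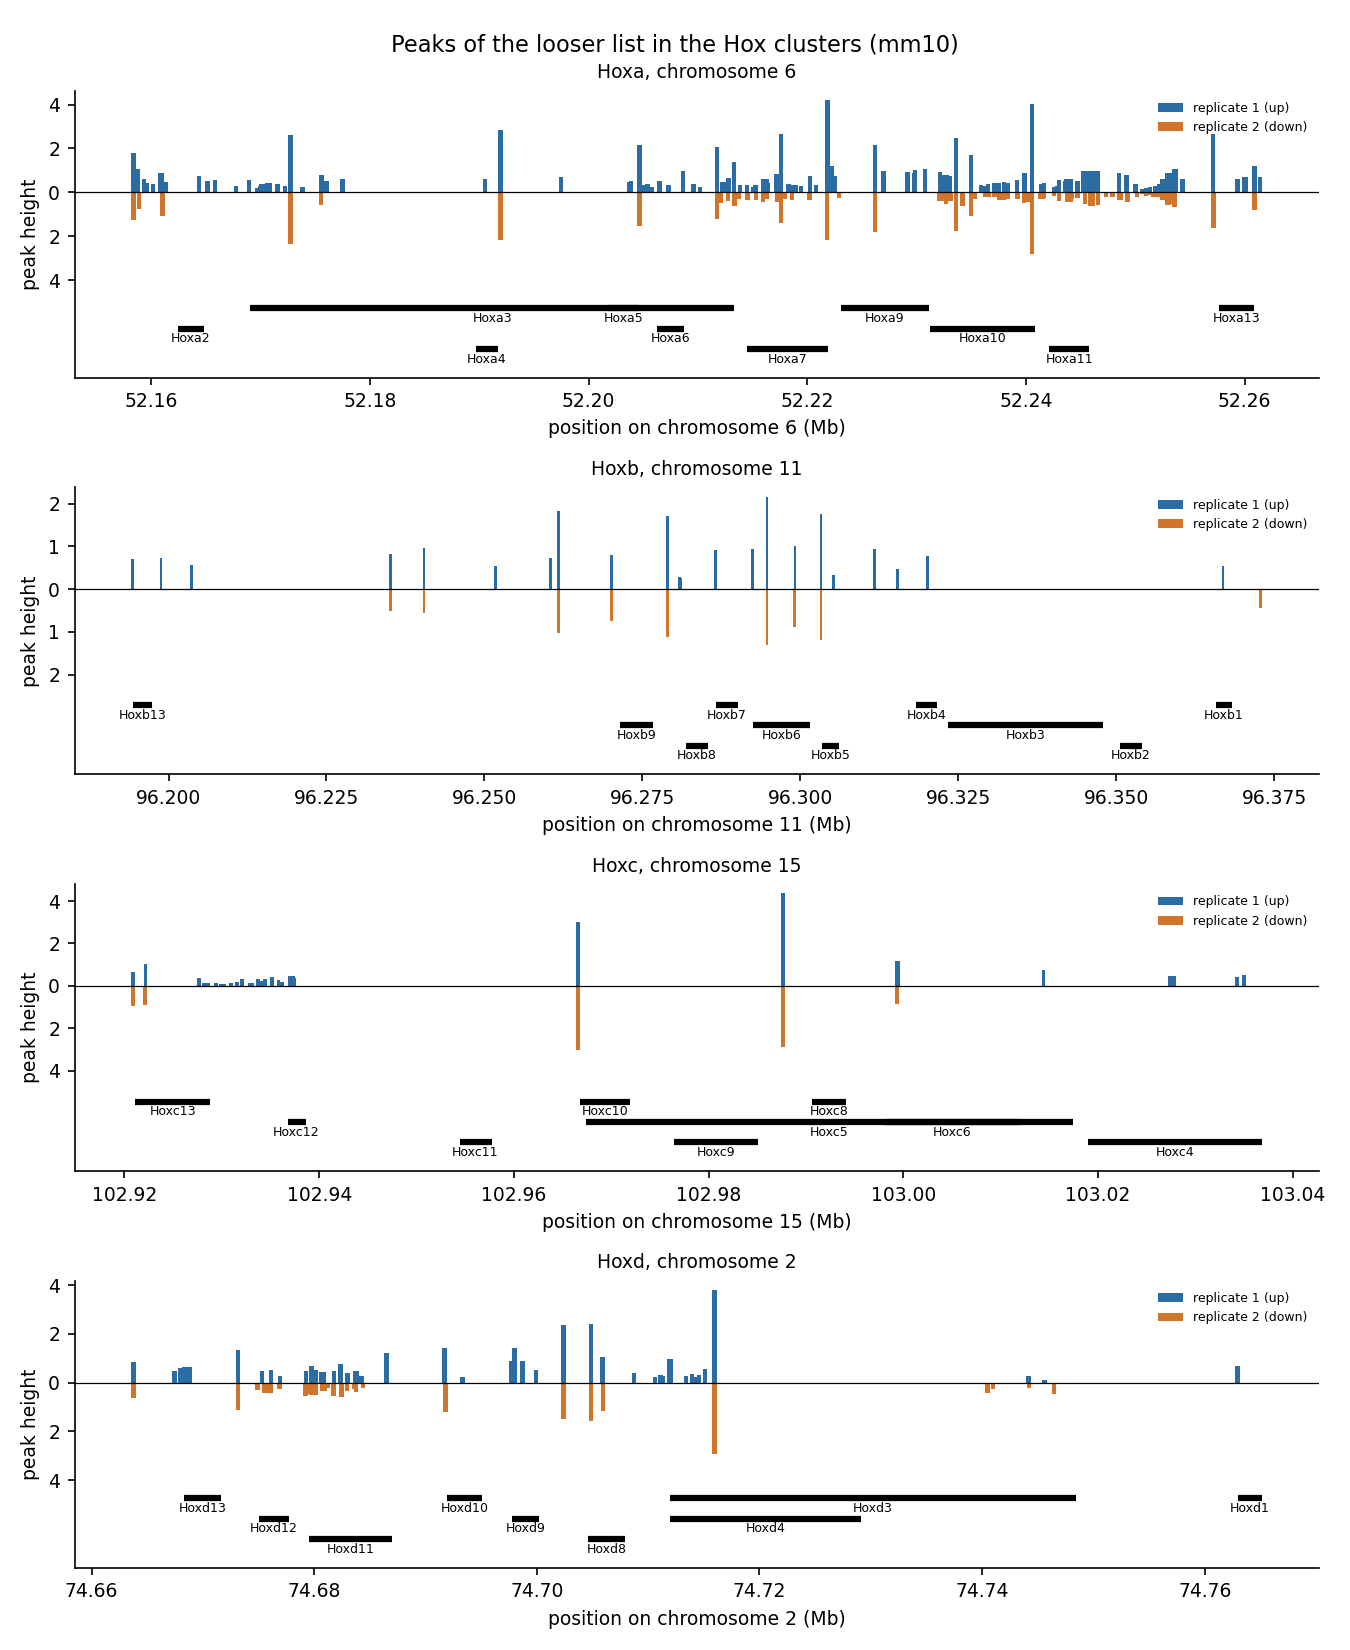
Peaks of the looser lists in the 4 Hox clusters, with position on the chromosome in Mb (mm10) on the horizontal axis and peak height on the vertical axis, replicate 1 upward in blue and replicate 2 downward in orange, and the bodies of the genes reported here as black bars. Hoxa holds 52 shared regions and Hoxc 4.

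Away from promoters, 30703 shared regions lay over 1000 bp from any TSS, and 25833 of them were within 100 kb of the nearest protein-coding TSS. Regulatory regions around cell type genes were counted per gene for each list. The immediate early and stress genes had a median of 2.5 distal regions against 0 over all genes (permutation test with 10000 random lists, adjusted p = 0.0324), with 8 at Fos, 5 at Fosb, 5 at Ier2 and 4 at Klf4. No other list passed. The immediate early call held in the stricter lists (median 1.5, adjusted permutation p = 0.0252) and above the low point of heights (median 2.5, 0.0108). It ended in replicate 1 alone (median 4, permutation test, adjusted p = 0.0504), in replicate 2 alone (median 3.5, adjusted p = 0.216) and within 50 kb (median 2, adjusted p = 0.0936). By the mean in place of the median it ended too (adjusted p = 0.367), and the fibroblast and mesenchyme list passed instead, with 6.5 regions a gene against 1.94 in random lists (permutation test, adjusted p = 0.0288). That call ended in the stricter lists (adjusted permutation p = 0.0504), above the low point of heights (0.0612), within 50 kb (0.595), in replicate 1 alone (0.110) and in replicate 2 alone (0.545). In that list Twist2, a repressor of differentiation in mesenchyme, had 65 regions, of which 3 were above the low point of heights, and Col1a1 had 14 regions, all 14 above it. Among urothelial genes, Shh, the epithelial signal to the bladder mesenchyme, had 19 regions with 4 above it, and Grhl2 had 9 with 6 above it, though the list's median was 1.

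The genes with the most distal regions drew them mainly from low peaks. Odc1, the first enzyme of polyamine synthesis, had 71, of which 3 were above the low point of heights, and Zfp618 had 70 with 5, followed by Twist2 and by Mc3r with 63 and 3. Coro2b (53 and 13), Sik1, a salt-inducible kinase (53 and 10), Azin1, an inhibitor of Odc1's antizyme (50 and 11), Col23a1 (50 and 1), Nsun2, an RNA methyltransferase (48 and 0), and Zfp36l2 (47 and 9) completed the 10 genes. The tallest shared distal region lay in an exon 10.3 kb from the TSS of Cox14 (chromosome 15, 99735701 to 99736060), with heights of 51.7 and 60.6. Next were exonic regions near Ubqln1 (29.3 and 42.2) and Lars2 (26.6 and 23.8), a region near Gm10722 that was fully repeat-masked (100%, 33.0 and 13.8), and regions nearest to Igf2bp3, Gm21887, Atp23 (390 kb away), Il31ra, Pak3 and Jarid2. These heights stood far above the median tallest promoter peak (2.44 and 1.80). Whether these regions have copies elsewhere in the genome was not checked.

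**Figure D4:**
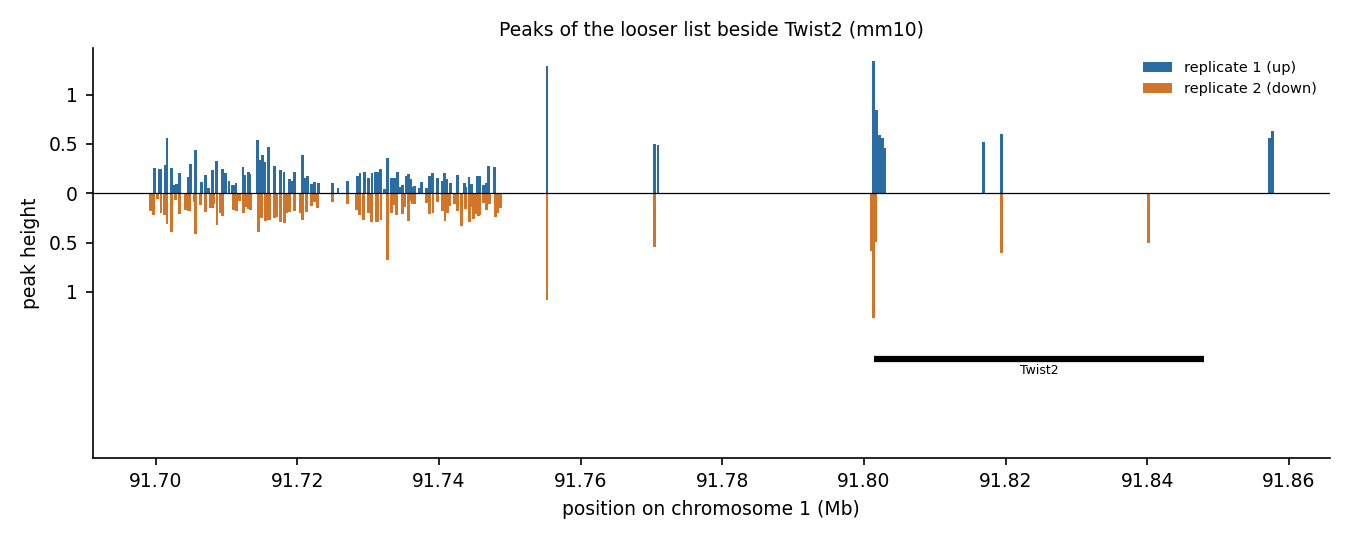
Peaks of the looser lists beside Twist2, with position on chromosome 1 in Mb (mm10) on the horizontal axis and peak height on the vertical axis, replicate 1 upward in blue and replicate 2 downward in orange, and the gene as a black bar. A run of low peaks lies upstream of the gene in both replicates, and the promoter peak reaches 1.34 and 1.27.

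REST and CTCF had the highest ratios of match frequency in the distal regions, among motifs with a match in shuffled sequence. Of 30 motifs, 21 were more frequent in the central 150 bp of shared distal regions than in shuffled sequence and 2 were less frequent, by 95% intervals for counting error only. The CTCF motif, bound by the main insulator protein, was in 13.4% of the 30703 windows against 0.476% of shuffled ones, 28.2 times as often (23.9 to 33.2), and 15.4 and 11.7 times in the regions of replicate 1 and replicate 2 alone. REST, a repressor of neuronal genes, had a ratio of 68.0 (16.8 to 275) that rests on 2 shuffled matches (175 and 150 in the replicates alone, and 34.0 against GC-matched windows outside peaks, where CTCF had 41.9). NFI had 6.22 (3.08 to 12.6), NRF1 6.64 (3.79 to 11.6), the cAMP response element 6.76 (4.07 to 11.3), MEF2, a muscle factor, 3.47 (1.95 to 6.16) and KLF 2.63 (2.46 to 2.80). In replicate 1 and replicate 2 alone, NFI had 3.53 and 5.13, the cAMP response element 3.06 and 3.33, and MEF2 2.40 and 1.88. Against the GC-matched windows KLF had 1.26, FOX 1.23 and the cAMP response element 2.13. P53 and P63 had 2.43 (1.59 to 3.72), with 1.51 and 1.40 in the replicates alone, and intervals that include 1 in windows of 300 bp (1.13, 0.844 to 1.51) and above the low point of heights (1.40, 0.789 to 2.48). Further ratios were FOX at 1.97 (1.70 to 2.29), TEAD at 1.64 (1.48 to 1.82), AP-1 at 1.48 (1.36 to 1.61) and SRF at 1.28 (1.06 to 1.56). GRHL (1.11, 0.909 to 1.35) and GATA (0.983, 0.847 to 1.14) had intervals that include 1, and TCF/LEF (0.834, 0.751 to 0.927) and TBX (0.688, 0.573 to 0.826) were below 1. The interval included 1 for TCF/LEF against GC-matched windows (0.944, 0.846 to 1.05) and for TBX above the low point of heights (0.784, 0.602 to 1.02). The SRF ratio was below 1 in either replicate alone (0.858 and 0.911), in windows of 300 bp (0.871) and above the low point of heights (0.979). The GRHL ratio was 0.853 and 0.774 in the replicates alone, 0.872 in windows of 300 bp and 1.40 against GC-matched windows outside peaks.

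Footprints are short stretches inside a peak that are protected from DNase I. The authors listed 217816 in replicate 1 and 189794 in replicate 2, of which 87.5% and 91.4% lay in peaks of the looser lists. Within shared regions, 51.6% of the footprints in replicate 1 and 64.9% of those in replicate 2 overlapped a footprint of the other, against 32.7% and 38.8% after moving them at random within their regions. CTCF matches were covered in 92.8% and 89.4% of cases, 1.71 (95% interval 1.67 to 1.76) and 1.86 (1.81 to 1.92) times as often as the positions mirrored about the region's midpoint. Matches of NFI (2.40 and 2.95 times), NRF1 (2.36 and 2.60), the cAMP response element (2.14 and 2.31), KLF (2.11 and 2.24), RFX (2.03 and 2.04), REST (1.71 and 1.80), ETS (1.43 and 1.55) and the E-box (1.19 and 1.21) were also covered more often in both replicates. AP-1 (0.60 and 0.487), TEAD (0.639 and 0.685), FOX (0.313 and 0.359), GRHL (0.429 and 0.556) and PU.1 (0.652 and 0.441) matches were covered less often in both. With any overlap counted, TEAD (0.892, 0.789 to 1.01, and 0.882, 0.770 to 1.01) and GRHL in replicate 2 (0.903, 0.643 to 1.27) no longer were. The remaining ratios were then nearer to 1 but stayed below it with their intervals, FOX at 0.491 and 0.563, AP-1 at 0.876 and 0.792 and PU.1 at 0.703 and 0.696. The other 14 motifs of the 28 tested differed in at most 1 replicate. Taken by replicate, 8 (replicate 1) and 10 (replicate 2) motifs were covered less often than the mirrored positions, and 9 and 11 when matches came from the regions of that replicate alone.

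**Figure D5:**
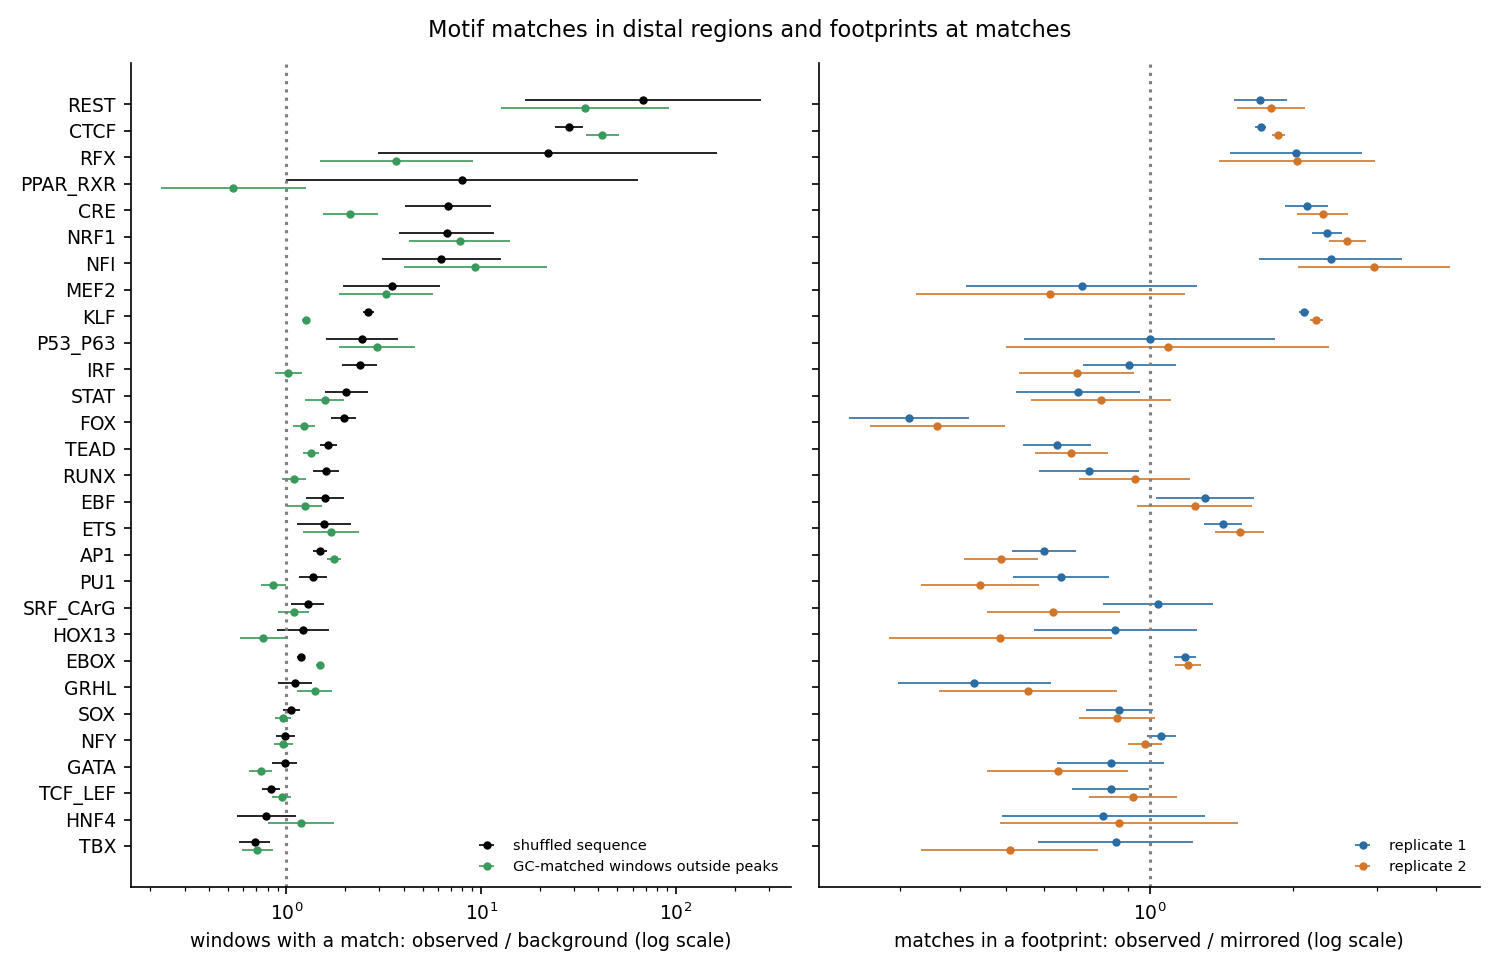
Left, ratio of windows with a match in shared distal regions to shuffled sequence (black) and to GC-matched windows outside peaks (green), and right, ratio of motif matches in a footprint to mirrored positions in replicate 1 (blue) and replicate 2 (orange). Axes are logarithmic, bars are 95% intervals for counting error only, and CTCF stands at 28.2 on the left and 1.71 and 1.86 on the right.

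The replicates, each n = 1, did not differ in height by cell type list in a way that passed adjustment. After centring on the shift of -0.28, the lists' promoters and distal regions gave 30 tests against 10000 random lists, of which 3 had an unadjusted permutation p under 0.05 and 0 an adjusted one (lowest adjusted p = 0.126). The 3 were adipocyte promoters, higher in replicate 2 by 0.27 (adjusted permutation p = 0.141), distal regions of kidney genes, higher by 0.45 (adjusted permutation p = 0.240), and distal regions of other endoderm genes, at -0.28 (adjusted permutation p = 0.126). With quantile normalization in place of centring, adipocyte promoters (0.35, adjusted permutation p = 0.0300) and distal regions of other endoderm genes (-0.34, adjusted permutation p = 0.0240) passed. In the stricter lists no list passed. Adipocyte promoters (-0.098) and distal regions of kidney genes (-0.0064) were then not higher in replicate 2, and distal regions of other endoderm genes stood at -0.45, with 3 genes each. The tallest peaks that overlapped none of the other replicate were nearest to Nhej1, Tarbp2, Hnrnpl, Phf13 and 1700029J07Rik in replicate 1 (heights 3.07 to 4.43) and to Gm21887, Duxf3, Sf1, Atf2 and Dad1 in replicate 2 (3.36 to 4.54). Each of them lay within 160 bp of a peak of the other replicate at least 2.96 high.

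The X chromosome had fewer peaks than the autosomes, and the Y chromosome nearly none, in these animals labelled female. Replicate 1 had 16.6 peaks per Mb on X (95% exact Poisson interval 16 to 17.2) and 39.1 on the autosomes, and replicate 2 had 25.2 (24.5 to 26.0) and 49.5. Relative to the autosomes, the density on X was 0.425 and 0.510. The Y chromosome held 72 peaks in replicate 1 and 77 in replicate 2, 0.817 (0.639 to 1.03) and 0.874 (0.690 to 1.09) per Mb. Kdm5d, Eif2s3y, Ddx3y and Uty, genes of the Y chromosome that male tissues express widely, had no promoter peak in either replicate. In the stricter lists the X chromosome stood at 0.302 of the autosomes, averaged over the replicates.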

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

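The tests of shared patches, of repeats and of a local threshold, and the tests of FOX and of AP-1 matches by themselves, were chosen only after the results they concern were seen.

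Much of the DNA with a listed false discovery rate lay outside the peaks. In replicate 1, 11.2 Mb of the 31.1 Mb with a listed rate of at most 0.05 was outside every peak of the looser list, and in replicate 2 it was 11.8 Mb of 34.5 Mb. This stood out because the bases are listed as past a threshold and yet no comparison in the report uses them.

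The genes with the most distal regions, Odc1, Zfp618 and Twist2, owed most of them to low peaks. Low peaks made up 38.2% of the stricter list in replicate 1 and 59.0% in replicate 2, and 81.8% and 84.9% of them lay in 1487 and 2660 patches with a median length of 6.73 and 7.14 kb. In replicate 1 the patch with the most peaks lay 77.5 kb from Twist2 (71 peaks, chromosome 1, 91699801 to 91748120). In replicate 2 it lay 106 kb from Dclk3, the nearest gene (91 peaks, chromosome 9, 111514989 to 111574240). Low peaks were proximal in 9.55% and 9.44% of cases, against 56.8% and 59.0% of tall ones, and were shared in 28.1% and 15.7%, against 74.0% and 88.3%.

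CTCF sites like those under tall peaks are argued against as the source of the low peaks. CTCF matches in low distal peaks were 0.832 (replicate 1, 95% interval 0.617 to 1.12) and 0.849 (replicate 2, 0.686 to 1.05) times as frequent as in shuffled sequence. In tall distal peaks they were 41.9 and 42.9 times as frequent. The comparison cannot decide on discrete elements without CTCF, since only 20.4% and 23.1% of tall distal peaks held a match. Other motifs were not tried in low peaks. Reads from annotated repeats are argued against as the main source, since 17.5% and 17.4% of the bases of low peaks were repeat-masked, below the 36.4% of the genome, though above the 6.29% and 6.38% of tall peaks. Broad open domains that both animals share stay open: 40.8% and 22.8% of patches overlapped a patch of the other replicate, far above 2.08% and 1.01% for shuffled patches but under 50%. A local threshold in the calling could also give such patches. Height alone did not decide which peaks the stricter list held. At log2 heights of -3 to -2.5 it held 7124 (replicate 1) and 14352 (replicate 2) peaks, where the looser list held 8700 and 16814. At -1.5 to -1 the stricter list held 1948 and 2379, where the looser held 11004 and 14324. Outside the patches, 91.1% and 89.0% of the peaks that the looser list alone holds were taller than the median low peak of the stricter list, values on either side of the 90% set for this test.

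Matches of AP-1, TEAD, FOX, GRHL and PU.1, factors of epithelium, muscle, mesenchyme and macrophages, were covered by footprints less often than mirrored positions. The ratios below count matches with at least 50% of their bases covered, and with any overlap counted they were nearer to 1 (FOX 0.491 and 0.563, AP-1 0.876 and 0.792). Low depth at their regions was examined in the tallest quartile of shared regions, where the median ratio over the 5 motifs was 0.518 and 0.429 (mean 0.473). The pattern thus held in tall regions too. This cannot decide on depth, since a match and its mirrored position lie in the same region. The base composition of the motifs is a candidate explanation, since the same strings read backwards gave median ratios of 0.756 and 0.733 (mean 0.744). For FOX it is argued against as the whole cause, and less clearly for AP-1. The FOX ratios were 0.313 and 0.359, below the intervals of the reversed string (0.897, 0.723 to 1.11, and 0.832, 0.648 to 1.07). Those of AP-1 were 0.60 and 0.487, also below (0.756, 0.634 to 0.901, and 0.734, 0.591 to 0.912). In replicate 1, though, the AP-1 ratio's own interval (0.513 to 0.701) overlapped that of the reversed string. In replicate 2 the AP-1 interval (0.407 to 0.582) lay below it. For TEAD and PU.1 base composition stays a candidate, since their reversed strings had ratios as low (0.602 and 0.593 for TEAD, 0.456 and 0.364 for PU.1). For GRHL the ratio lay below the interval of the reversed string in replicate 1 (0.429 against 0.650 to 1.05) and inside it in replicate 2 (0.556 against 0.555 to 0.968). No biological explanation was tested for this pattern, as the design gives no contrast.

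The Y chromosome held 72 and 77 peaks although the animals are labelled female. Male tissue is argued against, since 0 of the 4 promoters of Kdm5d, Eif2s3y, Ddx3y and Uty had a peak in either replicate. Reads from sequence with copies outside the Y chromosome are a likely source of part of them, since 62.5% (replicate 1) and 51.9% (replicate 2) of the peaks had an exact copy of their central 32 bases outside it, against 19.9% and 20.2% of random windows on the Y chromosome. For 18 and 26 peaks no other copy was found, and their source stays open. No biological explanation other than male tissue was tested for this pattern.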

How the results depend on the processing

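Calls by GC-matched random lists, peaks at or above the low point of heights, the mean in place of the median, and the stricter lists for footprints were chosen only after the results were seen. No paired analysis was possible because the samples form a single group. A stricter selection of footprints by the authors' value was not run, since that value is 0.01 throughout. The depth of the libraries is not given in the sources used here, which limits what can be said of low peaks. Where a value moved, the cause was not tested.

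With the stricter lists, replicate 1 had 61623 and replicate 2 had 77545 peaks, r was 0.974, and locations were 50.7% proximal, 4.05% exonic, 20.6% intronic and 24.6% intergenic. X had 8.60 peaks per Mb (0.302 of the autosomes) and Y 0.539, promoter peaks stood at 1 Hoxb, 1 Hoxc and 2 Hoxd genes, and 65.4% and 66.6% of footprints lay in peaks. At or above the low point of heights there were 57845 and 47382 peaks, 70.5% and 86.6% of them shared, with r of 0.949. Locations were then 51.0%, 4.05%, 21.9% and 23.0%, X had 7.92 per Mb (0.371 of the autosomes) and Y 0.244 (0.0116), the Hoxa density was 2.18, and 1 motif was below background. A reciprocal overlap of 50% gave 46.0% and 36.1% of peaks shared, r of 0.968, and 38.7% and 46.8% of footprints shared, where footprints moved at random gave 11% and 13%. Equal numbers of the tallest peaks gave 56.3% in replicate 2. Within 2500 bp of a TSS, 51.2% of regions were proximal, 3.11% exonic and 19.8% intronic.

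With 1 replicate left out, proximal shares were 27.2% to 33.0%, exonic 5.56% to 5.59%, intronic 28.9% to 30.6% and intergenic 32.5% to 36.6%. The number of lists below the other genes was 5 (without replicate 1) to 6 (without replicate 2), against 8 with both, and of lists with more distal regions 0 to 0, against 1. Densities of regions per 10 kb were 6.17 to 9.21 (Hoxa), 0.460 to 1.15 (Hoxb), 0.346 to 2.25 (Hoxc) and 2.48 to 3.82 (Hoxd), with promoter peaks at 2 to 4 Hoxb, 2 to 4 Hoxc and 4 to 9 Hoxd genes. The higher value of each range of Hox clusters came without replicate 2. Motifs below background numbered 4 to 4, against 2, and motifs footprinted less often than mirrored positions 9 (without replicate 2) to 11 (without replicate 1). With matches in shared regions the counts were 8 in replicate 1, 10 in replicate 2 and 5 in both. The ratio was 0.774 to 0.853 for GRHL and 0.858 to 0.911 for SRF, against 1.11 and 1.28 with both.

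Against GC-matched random lists, 2 lists were above, where 4 were above the other genes. Distal assignment within 50 kb left 0 lists past the threshold, and quantile normalization gave 2 lists with a difference between replicates, where centring gave 0. A motif is said to turn only where the ratio crossed 1 and its interval excluded 1 before or after; further ratios crossed 1 with intervals that included 1 both times, as for HNF4 and SOX against GC-matched windows. GC-matched windows gave 4 motifs below background and in this sense turned HOX13 (0.756), PU.1 (0.858) and PPAR/RXR (0.533). Windows of 300 bp gave 5 below background and turned GRHL (0.872) and SRF (0.871), and SRF turned at or above the low point of heights too (0.979). With any overlap counted, the NFY ratio of footprints in replicate 2 was 1.11.

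Over all alternatives and named genes or motifs, calls for promoter lists ended in 11 and were gained in 5 of the tests, with 102 on the same side. For distal regions these counts were 4, 1 and 106, for differences between replicates 0, 2 and 84, for motifs 7, 4 and 126 with 10 turned in the sense above, and for footprints at motifs 9, 8 and 98 with 1 turned. For promoter lists and distal regions, the counts on the same side also include summary values, such as the number of lists past the threshold. They therefore overstate how many tests of single lists kept their call.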

Other observations

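The signalling lists, the counts above the low point of heights and the taste and olfactory receptor list were chosen only after the data were seen.

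Among Hedgehog genes, which carry a signal from epithelium to mesenchyme, the promoters of the receptor genes Ptch1 (1.58 in replicate 1 and 1.27 in replicate 2), Smo (2.12 and 1.95) and Gas1 (3.17 and 2.38), the inhibitor gene Sufu (5.32 and 4.04) and the transcription factor gene Gli2 (2.15 and 1.74) had peaks in both replicates. The ligand genes Shh, Ihh and Dhh had none, and of the 14 genes 11 were open (78.6%, Fisher's exact test, adjusted p = 0.330 over 6 lists), where GC-matched random lists had 83.1% (adjusted p = 1). Ligand and receptor genes were not compared by a test. Gli2 had 8 distal regions, all 8 above the low point of heights. Of the BMP and TGF-beta genes, 17 of 18 were open (94.4%, Fisher's exact test, adjusted p = 0.00903), though random lists matched on promoter GC had 78.6% on average (adjusted p = 0.230). The receptor gene Tgfbr1 was the tallest (6.61 and 4.92), followed by the target gene Id3 (4.15 and 3.03), the ligand gene Tgfb3 (3.83 and 2.76) and Smad3 (3.39 and 3.04). The ligand gene Bmp5 had no promoter peak, and the inhibitory Smad6 had 13 distal regions, 12 of them above the low point.

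In the Wnt list 16 of 18 promoters were open (88.9%, Fisher's exact test, adjusted p = 0.0512), among them the receptor genes Fzd1 (3.38 and 2.66) and Fzd7 (3.36 and 2.76) and the feedback gene Axin2 (2.85 and 2.17), and not the ligand genes Wnt7b and Wnt9b. The Notch list had 11 of 13 (84.6%, Fisher's exact test, adjusted p = 0.225), with the nuclear effector Rbpj (5.80 and 3.64) and the targets Hey2 (5.63 and 3.44), Hey1 (3.23 and 2.23) and Hes1 (2.85 and 2.67). Of the retinoic acid genes, 9 of 13 were open (69.2%, Fisher's exact test, adjusted p = 0.778), with Rxrb at 6.52 and 4.97, Rarg at 4.37 and 1.13, and Cyp26b1, which breaks retinoic acid down, at 0.820 and 0.792. Rxra had 18 distal regions, all 18 above the low point, and Cyp26b1 had 9, of which 3 were. Random lists matched on promoter GC had a peak at 84.5% (Wnt), 83.5% (Notch) and 77.9% (retinoic acid) of genes on average. Against them, none of these lists passed. No taste or olfactory receptor gene was open (0 of 9, Fisher's exact test, adjusted p = 0.000918, and 0.0264 against random lists matched on promoter GC).

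Counted above the low point of heights, genes with many distal regions were 4930467E23Rik (24 of 25), Sfi1 (24 of 24), Bcor (21 of 23), Mroh2a (21 of 23), Gm21887 (19 of 22), Gse1 (18 of 18), Rxra (18 of 18), Btbd35f29 (17 of 18) and Gm15319 (17 of 24). Whether these regions have copies elsewhere in the genome was not checked, so the counts need not reflect separate regulatory sites. Bcor, a corepressor gene, and Rxra, a nuclear receptor gene, are absent from the 10 genes led by Odc1 that low peaks brought to the top. For the fibroblast and mesenchyme list, the mean of 6.5 regions a gene, against 1.94 in random lists (permutation test, adjusted p = 0.0288), was 2.7 against 1.22 above the low point (adjusted permutation p = 0.0612). Twist2 alone had 65 regions, 3 of them above it.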
